A study of Homo sapiens with 6 samples.

How the data were processed

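RNA was taken from 6 flasks of CCD-18Co cells grown to 80% confluency in medium with 10% serum, 3 given vehicle and 3 given IL-33 at 10 ng/ml for 6 h, per the labels' protocols. Groups were read from the sample labels. Replicate numbers name the libraries in order and pair nothing across groups. RNA was isolated with a column kit and made into Illumina libraries, per the labels' protocols. The submitters' processing notes name TopHat, Cufflinks, Cuffdiff and the human genome build hg19, without versions or roles, and whether the libraries kept strand is not given in the sources used here.

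The deposited files are Cufflinks transcript files, 1 per library, that hold FPKM (fragments scaled by transcript length and by the library's fragments), its lower and upper confidence bounds, a coverage and an isoform fraction for each of 41138 RefSeq transcripts of 23284 gene names. These values are named in the attribute field of the file lines and are here called FPKM, per the file headers and attribute names; the score column of the deposited files was not used. FPKM was normalized by the authors' software within each library, so values are relative within a library and hold no absolute RNA amount. The sum of FPKM lay between 416255 and 426254 per library. The transcript models were identical in all 6 files. The files hold no read counts, but for single-transcript genes the square of FPKM over its SD, taken from the distance to the upper bound, gave numbers near whole fragments. Of 20704 low values 83.1% lay within 0.02 of a whole number, where chance gives 4%. From these, depth was estimated gene by gene, and a high percentile of the estimates, not their centre, was taken as the library's depth. It was about 18000000, 16000000 and 16000000 fragments for vehicle replicates 1 to 3 and 18700000, 16400000 and 17300000 for IL-33 replicates 1 to 3. The median tested single-transcript gene rested on 356 fragments per library, and 20% of such genes on under 100, where counting error adds to the spread between flasks.

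A gene's FPKM was the sum over its transcripts. A gene was tested if its mean over the 6 libraries was at least 0.5 FPKM and its longest transcript at least 300 nucleotides, since FPKM of shorter transcripts depends on the fragment length model. Values were tested as log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (moderated test with an intensity trend, IL-33 against vehicle, no covariates), and p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Fold changes on that scale understate the change of genes at low values; ratios given as folds are ratios of mean FPKM. Values printed as mean ± SD are over the 3 libraries of a group. With 3 libraries against 3 an exact permutation test cannot go below 0.1, so calls rest on limma's pooled estimate of the spread. Flasks were separate cultures of 1 line handled by 1 laboratory, and the labels give no batch. The highest share of identical values above 0 between a pair of libraries was 0%.

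The 32 gene lists were fixed before the data were examined: 20 pathway lists, 4 lists on RNA quality or stress and 8 of cell type markers, with 689 members in all, of which 1 was matched through an older symbol and 0 were unmatched. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The named genes were also set by a rule beforehand: IL1RL1, IL1RAP and IL33; the 10 largest increases and 10 largest decreases among genes with an adjusted p under 0.05, a mean of at least 1 FPKM in the higher group and no overlap between the groups' libraries; and up to 4 members of smallest p from each list. NFKBIA, TNFAIP3, IL6, ACTA2, COL1A1, COL3A1, IL1RN, ALDOA, CCNB1, PLK1, AURKA, BUB1 and the ranking of genes above 0 in all 6 libraries were chosen after their values were seen, as were the genes named under the abundance minimum. The same holds for the other mitotic genes named with the cell cycle list. Some well expressed genes are listed at exactly 0 FPKM in single libraries, which can be a failed estimate, so such genes are given by library and without a fold. Genes overlap when their exons share at least 1 nucleotide on either strand.

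The gene test was tried on simulated data with the real genes' means and spread, 11945 genes of which 200 changed. It recovered 44% of genes changed 1.3-fold, 76% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, with 10 false calls (5.9% of the calls). The simulated noise was normal, independent between genes and equal in both groups, as the test assumes. The result thus describes the test under its own model and gives no error rate for the calls in the data. Alternatives fixed beforehand were other pseudocounts, other minimums of abundance and length, other scalings (a common sum, median-of-ratios, quantile), other variance models (no trend, robust, vooma, array weights), a test against a 1.2-fold change, the most abundant transcript in place of the sum, and each library left out in turn. Chosen after seeing the data were the removal of genes with a listed 0, the summing of overlapping genes, and voom on the implied fragments of single-transcript genes. Y-linked genes and XIST are not reported. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.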

Results

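Gene expression was measured by RNA sequencing in CCD-18Co cells, an established line of human colonic myofibroblasts, the contractile, matrix-producing cells that lie beneath the intestinal epithelium. The treated group held 3 flasks given 10 ng/ml recombinant human IL-33 for 6 h, and the control group held 3 flasks given vehicle, phosphate-buffered saline. IL-33 is a cytokine of the IL-1 family whose receptor chain is encoded by IL1RL1 and whose co-receptor is encoded by IL1RAP. Each library came from its own flask of the same line, so the replicates are cultures and not donors. The series as a whole concerns the activation of tumor stroma by IL-33 in intestinal polyposis, and the comparison here asks which transcripts of these stromal cells differed after IL-33. The depth recovered from the deposited values, a high percentile of single-gene estimates, lay between 16000000 and 18700000 fragments per library. Between 15768 and 16007 genes had a value above 0. Across genes, Pearson's r of log2 values was 0.992 to 0.993 within vehicle, 0.989 within IL-33 and 0.969 to 0.975 between the groups, where genes are not independent replicates. The leading principal component held 65% of the variance and placed the 3 vehicle libraries apart from the 3 IL-33 libraries. The second held 11.4%, with vehicle libraries from -4.84 to 3.06 and IL-33 libraries from -17.08 to 15.53. The IL-33 libraries thus lay further apart there, while limma's pooled estimate takes the spread as equal in both groups.

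After IL-33 the cells carried more mRNA for many secreted growth factors, matrix proteases and genes that respond to TGF-beta, and less for several chemokines, DNA replication factors and interferon-response genes. CBLN2, which encodes a secreted protein of the cerebellin family, rose from 0.718 ± 0.0847 to 14.1 ± 1.29 FPKM (SD, n = 3 per group), a ratio of 19.7. AREG, the gene of the epidermal growth factor receptor ligand amphiregulin, rose from 1.62 ± 0.273 to 20.4 ± 3.001 FPKM (n = 3 per group). SPHK1, the gene of sphingosine kinase 1, rose 12.6-fold and ANGPTL4, a secreted regulator of lipoprotein lipase, 14.1-fold. In the opposite direction, the neutrophil chemokine gene CXCL1 fell from 154.5 ± 2.51 to 40.2 ± 8.77 FPKM and the growth factor gene BMP4 from 94.5 ± 4.29 to 27.5 ± 5.05 FPKM (SD, n = 3 per group).

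Of 11945 genes tested with limma at a Benjamini-Hochberg adjusted p under 0.05, 1378 were higher and 3141 lower with IL-33, together 37.8% of the genes. At least 1.5-fold on the log2(FPKM + 0.5) scale, 467 of these were higher and 722 lower, and at least 2-fold, 189 were higher and 117 lower. The 3 libraries of one group lay wholly above those of the other for 6165 genes (51.6%), where chance gives 10%. Higher genes made up 30.5% of the calls on the deposited scale, and 50% after median-of-ratios scaling, with 1978 higher and 1975 lower genes. Over all tested genes the median log2 fold change was -0.10 as deposited and -0.01 after that scaling. Both scalings called 1376 of the same genes higher and 1975 of the same genes lower, and 0 genes in opposite directions.

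Among genes above 0 in all 6 libraries, ranked after their values were seen, the 10 largest increases on the log2(FPKM + 0.5) scale included CBLN2, ANGPTL4, SPHK1, AREG, IL11, DKK1, OLFM2, CDKN2B and ADAM19. IL11, a cytokine of the IL-6 family, rose from 21.1 ± 0.130 to 151.8 ± 36.3 FPKM (SD, n = 3 per group). DKK1, a secreted Wnt antagonist, rose 5.95-fold, CDKN2B, an inhibitor of cyclin-dependent kinases, 6.47-fold, and the metalloprotease gene ADAM19 5.33-fold. OLFM2 rose from 0.196 ± 0.0922 to 3.22 ± 0.480 FPKM (n = 3 per group). The 10 largest decreases were those of RASL11A, C10orf10, CXCL1, ADAMTS9, BMP4, VCAM1, IL6R, CD200, PMP22 and CEBPD. RASL11A fell from 17.8 ± 1.42 to 3.02 ± 1.14 FPKM, VCAM1, a leukocyte adhesion molecule, from 11.2 ± 0.596 to 3.14 ± 1.69 FPKM, and PMP22 from 220.5 ± 6.60 to 74.1 ± 8.77 FPKM (SD, n = 3 per group). Adjusted p-values from limma for the genes named here ranged from 1.86e-07 for CBLN2 to 0.00119 for VCAM1. CBLN2 lies on chromosome 18 from 70203915 to 70211723, CXCL1 on chromosome 4 from 74735109 to 74737019 and BMP4 on chromosome 14 from 54416455 to 54423554 (hg19). AREG is given by the files as 2 transcripts within chromosome 4 from 75310853 to 75490485, copies of a duplicated gene whose reads cannot be told apart, and its value is their sum.

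**Figure D1:**
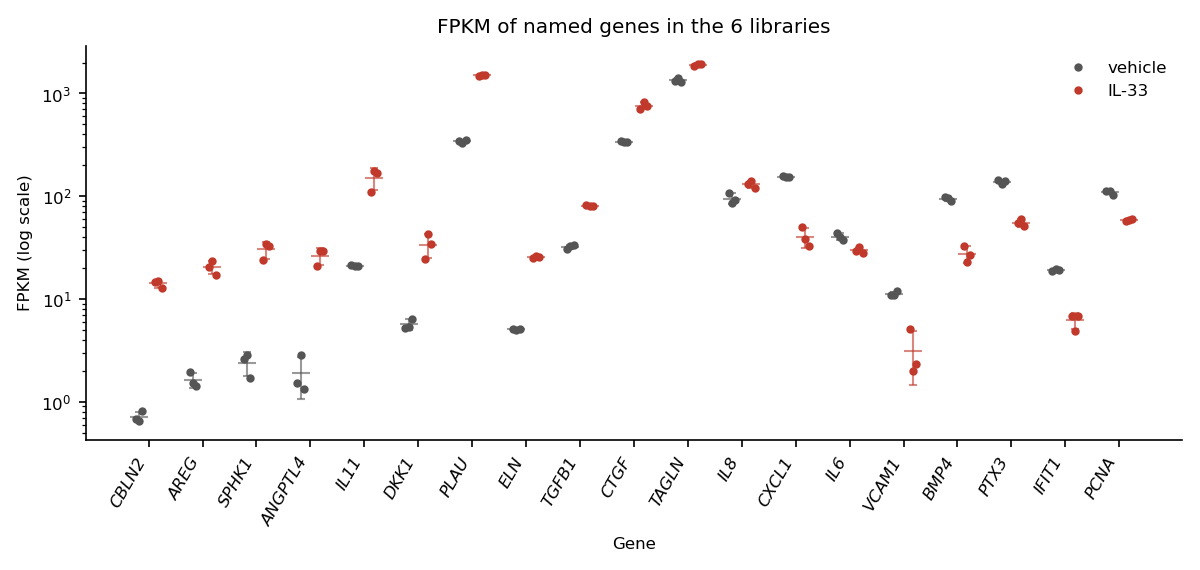
FPKM on a log axis of 19 genes in each of the 3 vehicle and 3 IL-33 libraries (points), with the group mean (horizontal bar) and SD (whiskers, n = 3). For each gene shown, all 3 libraries of one group lie above all 3 of the other; CXCL1 sits near 154.5 FPKM in vehicle and between 32.5 and 49.7 FPKM with IL-33.

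Among the 10 largest increases and 10 largest decreases by the rule fixed for naming genes were 14 genes that the files list at exactly 0 in some libraries; CSF2, picked from a gene list, has a listed 0 too and is given with the cytokines. ENDOV was listed at 0 in the 3 vehicle libraries and at 12.1, 10.3 and 11.1 FPKM in the IL-33 libraries. DLG4 was listed at 0 in vehicle and at 10.4, 8.001 and 8.46 FPKM with IL-33, PDSS1 at 0 and at 3.47, 6.94 and 2.73 FPKM, and TRIM6 at 0 and at 3.14, 3.57 and 3.46 FPKM. MSC was listed at 0, 22.5 and 0 FPKM in vehicle and at 38.7, 37.0 and 37.8 FPKM with IL-33. Listed at 0 in the 3 IL-33 libraries were MXD3 (11.3, 13.3 and 10.1 FPKM in vehicle), HOXB-AS3 (8.32, 8.50 and 8.64), C18orf8 (7.04, 6.17 and 6.08), CUTC (6.03, 4.76 and 5.75) and SEMA4G (2.31, 2.62 and 2.66). With IL-33, RFC4 was listed at 0, 0 and 11.9 FPKM against 15.9, 15.8 and 15.0 in vehicle, and NIT1 at 0, 0 and 10.4 FPKM against 14.0, 15.2 and 11.8. RAD17 was listed at 0, 0 and 4.46 FPKM against 6.09, 4.96 and 5.42, and SHMT1 at 0, 1.78 and 0 FPKM against 4.34, 3.005 and 4.48. All 14 share exon sequence with another annotated gene. Summed over the genes that overlap at the locus, 7 of the 14, DLG4, PDSS1, TRIM6, MXD3, C18orf8, NIT1 and SEMA4G, changed sign, TRIM6 with a call in the opposite direction and the others without a call, RAD17 no longer passed, and ENDOV, MSC, HOXB-AS3, CUTC, RFC4 and SHMT1 passed in the same direction with smaller log2 changes (1.4 for ENDOV, 0.56 for MSC, -0.35 for HOXB-AS3, -0.38 for CUTC, -0.36 for RFC4 and -0.68 for SHMT1, from 4.54, 4.42, -4.17, -3.58, -3.46 and -2.40). MSC lost its call when any library other than vehicle replicate 2 was left out (adjusted p from limma 0.0529 to 0.0887; 5.38e-08 to 0.134 over all alternatives), and RFC4, NIT1 and RAD17 when any library other than IL-33 replicate 3 was left out (0.0715 to 0.106; 2.93e-07 to 0.755 over all alternatives).

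The IL-33 receptor gene itself was expressed at a low level, and the deposited estimates assigned nearly all of its fragments to the transcript of the soluble receptor. IL1RL1 has 2 transcripts in the files, both on chromosome 2 (hg19). Exons 2 to 7 are the same in both, so the split of fragments between them is an estimate. NM_016232 (102927962 to 102968497, 11 exons) encodes the membrane receptor, and NM_003856 (102953717 to 102961182, 8 exons) uses another first exon, ends in an extended exon 8 and encodes the soluble decoy form. NM_003856 was at 0.131 ± 0.026 FPKM in vehicle and 0.606 ± 0.125 FPKM with IL-33 (SD, n = 3 per group), a ratio of 4.63 that rests on about 15 and 75 fragments in all. The 3 IL-33 libraries lay above the 3 vehicle libraries, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. NM_016232 was listed at 0.044 FPKM in vehicle replicate 1, about 1 fragment, and at 0 in the other 5 libraries, so a difference in the membrane form was not detectable at this depth. As a gene IL1RL1 was under the abundance minimum and entered no limma test. IL1RAP was at 3.31 ± 0.170 FPKM in vehicle and 4.22 ± 1.196 FPKM with IL-33 (SD, n = 3 per group; limma adjusted p = 0.219). It passed when IL-33 replicate 3 was left out (adjusted p = 0.0225; 0.0225 to 1 over all alternatives). IL33 was at 0, 0.0286 and 0.0286 FPKM in vehicle and 0.0732, 0.0279 and 0.0264 FPKM with IL-33.

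**Figure D2:**
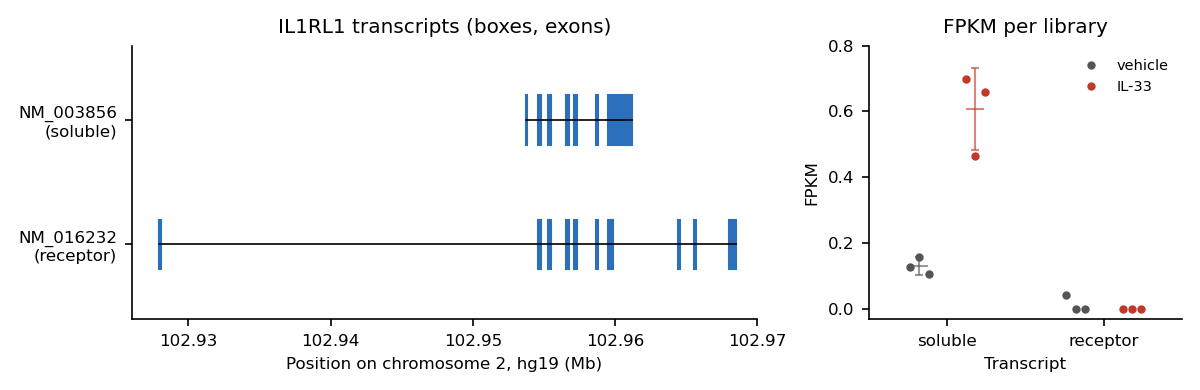
Left, exons (boxes) of the IL1RL1 transcripts NM_003856 and NM_016232 against position on chromosome 2 (hg19, Mb); right, FPKM of each transcript in the 3 vehicle and 3 IL-33 libraries (points), with mean and SD (n = 3) for NM_003856. The soluble form lies between 0.106 and 0.158 FPKM in vehicle and between 0.464 and 0.697 FPKM with IL-33, and the receptor form is at 0 in 5 of the 6 libraries.

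Many genes that respond to TGF-beta rose. Of the 22 members of the TGF-beta response list, 12 rose, 2 fell and 8 did not pass (13 higher and 2 lower adjusted over the list alone), and the list median was 0.91 on the log2 scale. PMEPA1, a feedback inhibitor of TGF-beta signalling, rose from 2.35 ± 0.0875 to 11.9 ± 0.486 FPKM and TGFBI, a secreted matrix protein, from 220.6 ± 2.49 to 486.4 ± 16.0 FPKM (SD, n = 3 per group). IL11 and CDKN2B, given above, belong to this list too. The camera test with a preset correlation of 0.01 gave this list the lowest adjusted p of the 32 lists, 2.11e-09, and the adjusted p = 0.0635 with an estimated correlation. TGFB1 itself, on chromosome 19 from 41836812 to 41859831, rose from 32.3 ± 1.46 to 80.9 ± 0.905 FPKM (limma adjusted p = 2.27e-06).

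Growth factor genes rose as a group too. In the list of epithelial and vascular growth factors 14 of 19 tested members rose and 3 fell (camera adjusted p = 9.2e-09; adjusted p = 0.292 with an estimated correlation). Beside AREG, TGFB1 and ANGPTL4, VEGFC, a lymphatic growth factor and the remaining member among the 4 of smallest p, rose from 17.9 ± 0.407 to 47.6 ± 6.70 FPKM (SD, n = 3 per group). In the list of Wnt, R-spondin and BMP niche factors 7 of 23 rose and 6 fell (8 and 6 adjusted over the list alone, 9 and 6 after median-of-ratios scaling). There FOXL1, a transcription factor gene of subepithelial mesenchyme, rose 2.21-fold and WNT5A 2.21-fold, beside the rise of DKK1 and the fall of BMP4. Its camera adjusted p was 0.0382, the adjusted p = 0.473 with an estimated correlation, and the adjusted p = 0.0868 when IL-33 replicate 1 was left out (0.0103 to 0.473 over all alternatives); median-of-ratios scaling, quantile normalization, a fit without an intensity trend and a test without a low-value filter ended the call too.

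Several genes of matrix proteases, their inhibitors and matrix proteins rose, and some fell. In the list of matrix proteases and inhibitors 15 of 27 rose and 5 fell (15 and 6 adjusted over the list alone, 17 and 2 after median-of-ratios scaling; camera adjusted p = 2.2e-06; adjusted p = 0.292 with an estimated correlation). PLAU, the gene of urokinase, rose from 343.2 ± 10.5 to 1501 ± 11.6 FPKM, its receptor gene PLAUR 3.25-fold, and SERPINE2, a protease inhibitor, 2.80-fold. ADAMTS9, given above among the largest decreases, belongs to this list and fell from 7.38 ± 0.154 to 1.78 ± 0.259 FPKM. In the list of fibrillar and basement membrane matrix genes 12 of 37 rose and 2 fell (12 and 3 adjusted over the list alone, 14 and 1 after median-of-ratios scaling). ELN, the elastin gene, rose from 5.09 ± 0.0497 to 25.7 ± 0.609 FPKM and TNC, the tenascin C gene, from 1.24 ± 0.127 to 7.89 ± 0.555 FPKM (SD, n = 3 per group), while COL4A1 rose 1.86-fold and COL7A1 2.15-fold. The main interstitial collagen genes, chosen after their values were seen, did not pass. COL1A1 was at 1379 ± 72.3 and 1470 ± 113.4 FPKM (limma adjusted p = 0.323), and COL3A1 at 505.8 ± 18.2 and 448.6 ± 49.3 FPKM (adjusted p = 0.102; 0.00968 without IL-33 replicate 1; 0.00968 to 1 over all alternatives). The median of this list was -0.03 and its mean 0.20. Its direction in the camera test was up relative to the other genes (adjusted p = 0.00354, and adjusted p = 0.633 with an estimated correlation). The median of all tested genes was -0.10. Without IL-33 replicate 1 the matrix list no longer passed (adjusted p = 0.0988; 0.00123 to 0.633 over all alternatives).

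Some contractile genes of the myofibroblast rose by small amounts. Of 22 members 8 rose, 1 fell and 13 did not pass (9 and 1 adjusted over the list alone, 11 and 0 after median-of-ratios scaling; camera adjusted p = 4.77e-05; adjusted p = 0.38 with an estimated correlation). The rises were 1.597-fold for SMTN, 1.55-fold for CNN1, 1.42-fold for TAGLN and 1.31-fold for TPM1. ACTA2, the smooth muscle actin gene and chosen after its values were seen, was at 839.3 ± 32.6 FPKM in vehicle and 895.4 ± 62.5 FPKM with IL-33 (SD, n = 3 per group; limma adjusted p = 0.273, and 0.043 after median-of-ratios scaling). In the list of adhesion and leukocyte contact molecules 9 of 20 rose and 5 fell (9 and 2 after median-of-ratios scaling; camera adjusted p = 0.0021; adjusted p = 0.578 with an estimated correlation). ITGA2, an integrin chain that binds collagen, rose 4.93-fold, CD274, the gene of the checkpoint ligand PD-L1, 3.32-fold, PDPN 1.94-fold and ITGB3 1.91-fold. Of the immediate-early genes 10 of 25 rose and 5 fell (11 and 5 adjusted over the list alone, 11 and 3 after median-of-ratios scaling; camera adjusted p = 0.00286; adjusted p = 0.292 with an estimated correlation). CTGF, the gene of connective tissue growth factor, rose 2.24-fold, FOSL1 1.71-fold and NR4A1 1.73-fold, and FOSL2 fell 1.80-fold.

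Inflammatory genes changed in both directions. In the NF-kB pathway and feedback list 9 of 19 rose and 2 fell (camera adjusted p = 0.00114; adjusted p = 0.254 with an estimated correlation). RELB, a subunit of NF-kB, rose 2.04-fold, NFKBIE, an inhibitor of it, 1.54-fold and IER3 1.39-fold, and SOD2 fell from 102 ± 2.59 to 73.6 ± 3.13 FPKM (SD, n = 3 per group). NFKBIA and TNFAIP3, which encode feedback inhibitors of NF-kB and were chosen after their values were seen, did not pass, at 12.7 ± 0.654 and 13.4 ± 1.24 FPKM for NFKBIA and 1.03 ± 0.123 and 1.21 ± 0.246 FPKM for TNFAIP3 (n = 3 per group). Of 9 chemokine genes tested 1 rose and 4 fell, and the list did not shift against other genes (camera adjusted p = 0.66). IL8, which encodes the neutrophil chemokine CXCL8, rose from 94.9 ± 11.5 to 131 ± 10.7 FPKM, while CXCL2 fell from 0.923 ± 0.0428 to 0.205 ± 0.0503 FPKM (SD, n = 3 per group). CCL2 fell from 2.05 ± 0.409 to 1.00 ± 0.392 FPKM, with its call lost without vehicle replicate 2 or 3 (adjusted p 0.056 and 0.0574; 0.00536 to 0.116 over all alternatives). Of 12 cytokine and colony-stimulating factor genes 4 rose and 5 fell (4 and 3 after median-of-ratios scaling; camera adjusted p = 0.333). IL11 and TNFSF15, the latter from 0.0427 ± 0.0257 to 1.24 ± 0.122 FPKM, rose, and CSF1, a macrophage growth factor, fell from 104.8 ± 1.72 to 65.7 ± 7.74 FPKM. CSF2, the gene of GM-CSF, passed as higher at 1.51, 3.05 and 2.31 FPKM with IL-33 against 0.185, 0 and 0.313 FPKM in vehicle. IL6, chosen after its values were seen, fell from 40.5 ± 2.99 to 29.8 ± 1.85 FPKM, and IL1RN, the IL-1 receptor antagonist gene chosen likewise, rose 5.22-fold.

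Several interferon-response genes fell. Of 36 members 16 fell and 1, IRF1, rose (18 and 1 adjusted over the list alone, 13 and 1 after median-of-ratios scaling; camera adjusted p = 0.0157; adjusted p = 0.7 with an estimated correlation). IFIT1 fell 3.08-fold and IFIT2 2.88-fold, and IRF1, a transcription factor of the same family of responses, rose 1.67-fold. Without IL-33 replicate 2 the list did not pass (adjusted p = 0.0619; 0.00127 to 0.7 over all alternatives). Among pattern receptors, complement and antimicrobial genes 0 of 11 rose and 3 fell (0 and 1 after median-of-ratios scaling; camera adjusted p = 0.268), and without IL-33 replicate 1 the list passed (adjusted p = 0.0179; 0.0179 to 0.752 over all alternatives). PTX3, a secreted pattern receptor, fell from 137.7 ± 6.36 to 55.3 ± 4.73 FPKM and C1QTNF1 1.29-fold, the latter without a call after median-of-ratios scaling (adjusted p = 0.0506). In the list of IL-33 receptor and proximal signalling genes 0 of 12 rose and 3, IRAK4, TAB1 and MYD88, fell (2 adjusted over the list alone; camera adjusted p = 0.686), against 2 higher and 2 lower after median-of-ratios scaling. IRAK4 fell 1.4-fold and TAB1 1.39-fold. MYD88, the adaptor of IL-1 family receptors, lost its call when any library but IL-33 replicate 1 was left out (adjusted p 0.0669 to 0.127; 0.00209 to 1 over all alternatives) and after median-of-ratios scaling. SIGIRR was at 5.18 ± 0.544 and 4.22 ± 0.458 FPKM (adjusted p = 0.0737).

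Many cell cycle genes, among them genes of DNA replication, were lower with IL-33. Of 32 members 24 fell, 0 rose and 8 did not pass (26 fell adjusted over the list alone, and 19 after median-of-ratios scaling). The list median was -0.46 on the log2 scale (camera adjusted p = 1.1e-06, and adjusted p = 0.638 with an estimated correlation). The groups' libraries overlapped for the mitotic genes CCNB1 (means of 51.6 and 49.7 FPKM), PLK1 (23 and 22.7) and AURKA (20.4 and 19.8). Those of AURKB and BUB1B overlapped too. The libraries of BUB1 (12.9 and 9.17 FPKM), CCNB2 (20.7 and 16.4) and CDK1 (41.1 and 28.9) all lay lower with IL-33. So did those of TOP2A, CDC20, CENPA, CENPF, BIRC5 and TTK. These mitotic genes were chosen after their values were seen. PCNA, the sliding clamp of DNA polymerase, fell from 109.9 ± 5.23 to 58.9 ± 1.55 FPKM (SD, n = 3 per group), the helicase genes MCM2 and MCM4 2.05-fold and 1.72-fold, and the cyclin gene CCNE2 2.10-fold. Among 15 other cyclins and arrest genes 4 rose and 5 fell (camera adjusted p = 0.66). Beside CDKN2B, TP53I3 rose 1.37-fold, and CDKN1C fell 2.39-fold and the D-type cyclin gene CCND2 1.42-fold.

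Metabolic and stress genes made up the remaining lists. Of 20 cholesterol and fatty acid synthesis genes 12 fell and 1 rose (camera adjusted p = 0.0354; adjusted p = 0.638 with an estimated correlation). LSS fell 1.56-fold, DHCR7 1.49-fold and FDFT1 1.45-fold. Without vehicle replicate 3 or IL-33 replicate 1 this list did not pass (adjusted p 0.0681 and 0.0868; 0.004 to 0.638 over all alternatives). Of 20 hypoxia and glycolysis genes 3 rose and 4 fell (4 and 2 after median-of-ratios scaling; camera adjusted p = 0.681), with PFKFB4 and PFKFB3, kinases that set the level of fructose 2,6-bisphosphate, higher by 4.41-fold and 1.95-fold and the glucose transporter gene SLC2A1 lower by 1.96-fold. P4HA1 fell 1.24-fold and lost its call without vehicle replicate 1 (adjusted p = 0.0581; 0.00969 to 0.963 over all alternatives) and after median-of-ratios scaling. In the unfolded protein response and amino acid stress list 7 of 19 rose and 5 fell (8 and 5 adjusted over the list alone, 9 and 2 after median-of-ratios scaling; camera adjusted p = 0.0157; adjusted p = 0.292 with an estimated correlation). The rises there were 1.87-fold for HERPUD1, 1.75-fold for PPP1R15A, 1.597-fold for the chaperone gene HSPA5 and 1.39-fold for CHAC1. In the prostaglandin list 3 of 12 rose and 3 fell (3 and 2 after median-of-ratios scaling; camera adjusted p = 0.703), with PTGS1, the gene of cyclooxygenase 1, 1.98-fold and the transporter gene SLCO2A1 1.73-fold higher, and the receptor gene PTGER4 2.55-fold and PTGES3 1.31-fold lower.

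**Figure D3:**
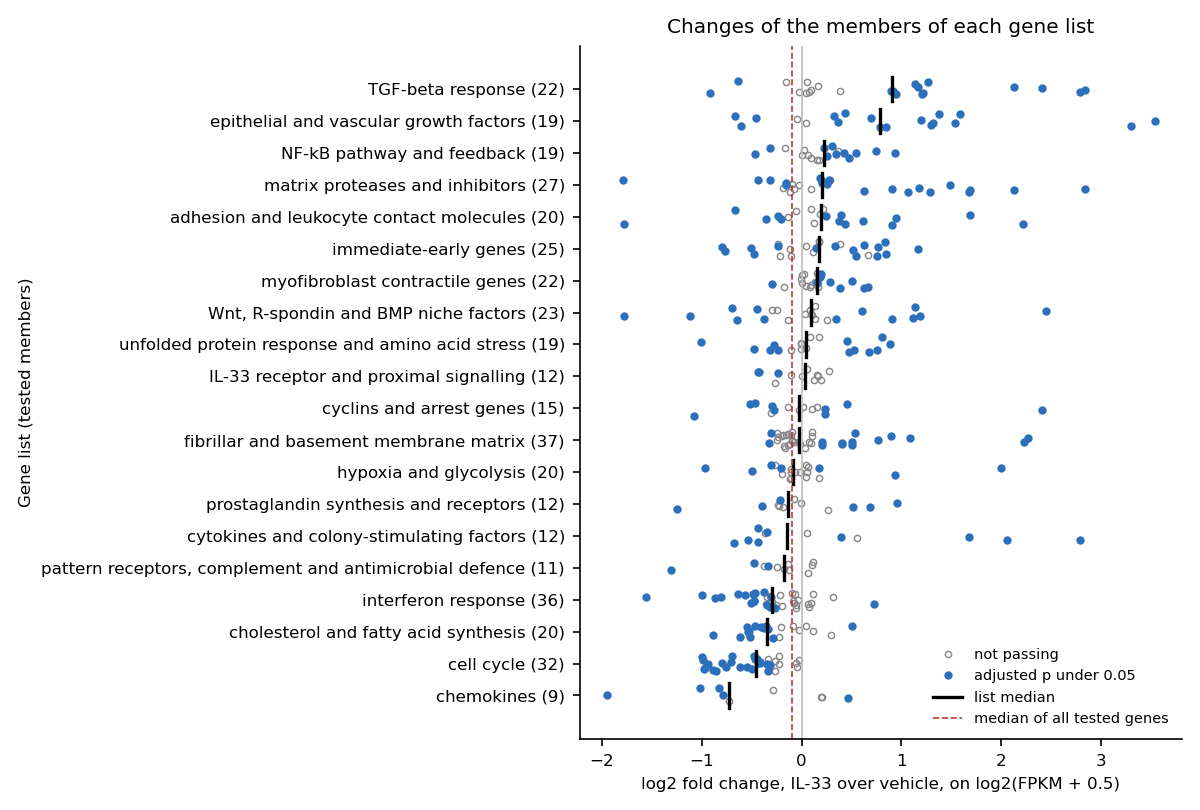
Log2 fold change (IL-33 over vehicle, on log2(FPKM + 0.5)) of each tested member of the 20 pathway lists, with the number tested in brackets, filled points at a limma adjusted p under 0.05, black bars at the list medians and a dashed line at the median of all tested genes, -0.10. The TGF-beta response list has a median of 0.91 and the cell cycle list a median of -0.46.

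Across all 32 lists, camera with the preset correlation called 14, of which 11 shifted up and 3 down relative to the other genes. With an estimated correlation camera called 0 lists, where the lowest adjusted p was 0.0635 and 4 lists had an unadjusted p under 0.05. Among the called lists the estimate was under the preset 0.01 for TGF-beta response (-0.017) and NF-kB (-0.033). It was above 0.01 for the others, up to 0.761 for ribosomal proteins. A higher correlation thus did not end the calls of the TGF-beta and NF-kB lists, and what else in that option did was not tested. The raw camera p of the TGF-beta list was 6.6e-11. The fry test, which does not compare a list with other genes, called 21 lists as moving in a direction and 25 as changing in either direction. The median, the mean or the camera direction differed in sign for the lists of IL-33 signalling (median 0.03, mean -0.04), cytokines (-0.15, 0.39), prostaglandins (-0.13, -0.01, direction up), matrix, cyclins and arrest genes (-0.02, 0.03), hypoxia (-0.08, 0.03), histones (-0.01, -0.11, direction up), epithelial markers (-0.11, -0.11, direction up) and leukocyte markers (-0.09, -0.09, direction up). After median-of-ratios scaling the medians of matrix (0.07), cyclins and arrest genes (0.08), hypoxia (0.02), histones (0.08) and housekeeping genes (0.02) turned positive. Counts adjusted over the list alone equalled those over all genes in 20 lists and differed in 12.

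The lists on RNA quality and stress differed from each other. All 36 cytosolic ribosomal protein genes were without a call in limma (0 at an unadjusted p under 0.05, and 4 higher after median-of-ratios scaling, among them RPS14, RPS9 and RPL4), with a list median of 0.02 that turned negative under quantile normalization (-0.02). Their camera adjusted p was 0.0382, the adjusted p = 0.769 with an estimated correlation, and the list did not pass without vehicle replicate 3, IL-33 replicate 1 or IL-33 replicate 3 (adjusted p 0.138 to 0.545; 5.75e-06 to 0.769 over all alternatives). Its members of smallest p were RPS14 (839.4 ± 14.2 and 905.4 ± 72.7 FPKM), RPS9 (533.6 ± 9.17 and 570.7 ± 37.0 FPKM), RPL4 (377.4 ± 9.62 and 397.9 ± 7.81 FPKM) and RPL15 (254.1 ± 8.26 and 238.8 ± 11.6 FPKM), and RPS14 and RPS9 passed without IL-33 replicate 2 (limma adjusted p 0.015 and 0.0307; 0.015 to 1 over all alternatives). Of 14 housekeeping genes 0 rose and 2, SDHA by 1.35-fold and EEF1A1 by 1.10-fold, fell (1 adjusted over the list alone; camera adjusted p = 0.686; 1 higher and 1 lower after median-of-ratios scaling). EEF1A1 lost its call without any 1 of the 3 vehicle libraries or without IL-33 replicate 3 (adjusted p 0.0743 to 0.147; 0.000445 to 1 over all alternatives) and after median-of-ratios scaling. HPRT1, at 17.7 ± 0.560 and 14.8 ± 2.21 FPKM, and TFRC, at 27.0 ± 1.69 and 22.5 ± 3.803 FPKM, passed as lower without IL-33 replicate 2 (adjusted p 0.0211 and 0.00503; 0.00503 to 1 over all alternatives). Metallothionein genes, which have near-identical copies, rose 4.28-fold (MT1E), 3.76-fold (MT2A) and 5.19-fold (MT1X), and GCLM, a glutathione synthesis gene, fell 2.37-fold. In their list of heat shock and metallothionein genes 5 of 17 rose and 6 fell (7 and 4 after median-of-ratios scaling; camera adjusted p = 0.154). Of 10 replication-dependent histone genes 0 rose and 2 fell (camera adjusted p = 0.843), HIST1H1C by 1.27-fold and HIST2H4A from 2.18 ± 0.540 to 1.04 ± 0.406 FPKM. HIST2H4A lost its call without vehicle replicate 1 or 3 (adjusted p 0.0792 and 0.0757; 0.0132 to 0.145 over all alternatives). HIST1H2BJ was at 1.62 ± 0.412 and 1.01 ± 0.427 FPKM and passed without IL-33 replicate 3 (adjusted p = 0.0427; 0.0427 to 0.638 over all alternatives), and HIST1H2BD at 4.52 ± 1.27 and 5.46 ± 0.607 FPKM passed without vehicle replicate 1 (adjusted p = 0.0191; 0.0191 to 1 over all alternatives).

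All 13 fibroblast markers had a mean of at least 1 FPKM, led by VIM at 1935 FPKM in vehicle and 1913 FPKM with IL-33, and 2 of them fell and 0 rose (camera adjusted p = 0.893; 2 higher and 1 lower after median-of-ratios scaling). DDR2 fell 1.39-fold and S100A4 1.22-fold, the latter without a call when vehicle replicate 1 or 3 was left out (adjusted p 0.0556 and 0.0641; 0.00105 to 1 over all alternatives). PDGFRB was at 51.2 ± 2.27 and 58.7 ± 4.39 FPKM (limma adjusted p = 0.0521; 0.0373 without IL-33 replicate 2; 0.0112 to 1 over all alternatives), and FAP at 1.91 ± 0.238 and 2.47 ± 0.223 FPKM (adjusted p = 0.0554). Of 9 pericyte and smooth muscle markers tested 2, CNN1 and ACTG2 (1.22-fold), rose and 2, MCAM (1.17-fold) and RGS5, fell (3 and 0 after median-of-ratios scaling; camera adjusted p = 0.238). RGS5, at 4.43 ± 0.240 and 3.28 ± 0.704 FPKM, lost its call when any library but IL-33 replicate 1 was left out (adjusted p 0.0592 to 0.136; 0.0184 to 0.664 over all alternatives). After median-of-ratios scaling S100A4, MCAM, RGS5, KRT19, CD14 and UCHL1 had no call, and PDGFRB, FAP and KRT18 passed as higher. Markers of other lineages were mostly near 0. Of 14 epithelial markers 2 reached 1 FPKM, KRT18 at 163.5 ± 7.06 and 180.6 ± 12.8 FPKM and KRT19 at 14.5 ± 0.681 and 11.3 ± 1.97 FPKM (list camera adjusted p = 0.843). KRT19 lost its call without any 1 vehicle library or IL-33 replicate 1 (adjusted p 0.0549 to 0.125; 0.0172 to 0.776 over all alternatives), and KRT18 passed without IL-33 replicate 2 (adjusted p = 0.0267; 0.0211 to 1 over all alternatives). Of 10 endothelial markers TEK alone was tested, at 6.64 ± 0.234 and 5.23 ± 0.997 FPKM (list camera adjusted p = 0.681; limma adjusted p for TEK 0.056, and 0.00588 without IL-33 replicate 1; 0.00588 to 0.945 over all alternatives). Of 12 leukocyte markers CORO1A alone was tested, at 1.85 ± 0.314 and 1.71 ± 0.156 FPKM (list camera adjusted p = 0.995). Of 10 macrophage markers CD14 and CD68 were tested (list camera adjusted p = 0.681), CD68 at 8.11 ± 0.151 and 7.65 ± 0.505 FPKM. CD14 fell from 15.4 ± 0.4002 to 11.1 ± 2.72 FPKM, a call lost without any 1 vehicle library or IL-33 replicate 3 (adjusted p 0.0598 to 0.0935; 0.00612 to 0.44 over all alternatives). Of 8 mast cell markers KIT, a receptor tyrosine kinase, fell from 8.69 ± 0.108 to 3.35 ± 0.990 FPKM, and GATA2 was at 7.09 ± 0.462 and 6.66 ± 0.264 FPKM (list camera adjusted p = 0.382). Of 8 enteric glia and neuron markers UCHL1 fell from 136.7 ± 4.89 to 118 ± 2.51 FPKM (adjusted p = 0.0114; 0.0568 without vehicle replicate 2; 0.0101 to 1 over all alternatives), and RET was at 1.16 ± 0.181 and 1.11 ± 0.138 FPKM (list camera adjusted p = 0.686).

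Transcripts were also tested singly. Of 15575 transcripts tested 835 were higher and 1561 lower with IL-33, in 2307 genes. Without vehicle replicate 1, 2 or 3 the number of changed transcripts fell from 2396 to 1022, 1023 and 991. In 24 genes at least 1 transcript rose while another fell. For ALDOA, the gene of the glycolytic enzyme aldolase A and chosen after its values were seen, NM_184041 was at 457.2, 482 and 437.7 FPKM in vehicle and 527.4, 522.9 and 561.8 FPKM with IL-33, while NM_184043 was at 56.8, 59.8 and 69.6 FPKM in vehicle and listed at 0 in the 3 IL-33 libraries. The split of reads between transcripts of 1 gene is an estimate of the deposited processing, and such listed zeros carry no fold.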

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

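The tests in this part were chosen after the values were seen. Genes under the abundance minimum of 0.5 FPKM entered none of the limma tests above. Apart from IL1RL1 and IL33, no values of them are given there. Implied fragments were tested only for such genes with a single transcript of at least 300 nucleotides. Of these single-transcript genes 1148 had at least 20 implied fragments in total. In 76 of these the IL-33 libraries all lay above the vehicle libraries and the fragments exceeded those in vehicle at an adjusted p under 0.05 (conditional binomial test on summed fragments, which covers counting error only), a signal in data the report does not use; 98 were lower in the same way. Above 0 in all 6 libraries were 63 of the higher and 89 of the lower genes. ADAMTS6, a metalloprotease gene, had 44 fragments in vehicle and 313 with IL-33, LAMA1, a basement membrane laminin chain, 101 and 303, HAS2, which makes hyaluronan, 12 and 114, and SOX8, a transcription factor gene, 13 and 117. The growth factor gene EREG, a relative of AREG, had 17 and 92, the decoy receptor gene IL13RA2 5 and 58, and COMP, a cartilage matrix gene, 21 and 86. Among the lower genes CELSR2 had 356 and 169 fragments and ST8SIA1 171 and 51. KIF24 (295 fragments in vehicle, listed at 0 in the 3 IL-33 libraries) and PPM1E (listed at 0 in vehicle, 202 fragments with IL-33) showed the all-or-none values described among the other observations.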

How the results depend on the processing

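Leaving out genes with a listed 0, summing overlapping genes and voom on implied fragments were chosen after seeing the data; voom called 829 single-transcript genes higher and 1679 lower, against 812 and 1694 of these in the main test. Of the other alternatives run, those to the count of changed genes stayed within 1.5 times of 4519 except the test against a 1.2-fold change, which left 1137 genes, 469 higher and 668 lower, because it asks for a larger change. Lower genes numbered 1975 after median-of-ratios scaling and 2059 after quantile normalization. With any library left out, changed genes numbered 3156 to 4260. Leaving out a vehicle library kept 68.9% to 69.7% of the calls tested in both, and leaving out an IL-33 library 84% to 85.5%. The 14 called lists fell to 0 with an estimated correlation, and quantile normalization turned the ribosomal protein median to -0.022 and ended the calls of the ribosomal, matrix, niche factor and unfolded protein response lists; median-of-ratios scaling ended that of the niche factors. Fitting without an intensity trend and testing without a low-value filter each left 12 lists, with the niche factor and ribosomal calls ended. Changed transcripts numbered 991 to 1899 with a library left out. The soluble IL1RL1 transcript changed by 0.81 on log2(FPKM + 0.5), 1.603 with 0.1 and 0.50 with 1, since a pseudocount weighs more on low values. Summed with overlapping genes, DLG4 came to -0.10, PDSS1 to -0.024, TRIM6 to -0.65 (adjusted p = 6.36e-05), MXD3 to 0.063, C18orf8 to 0.075, NIT1 to 0.13 and SEMA4G to 0.11. Over 144 named genes and all alternatives, 3017 values stayed on their side of the threshold in the same direction, 139 lost and 38 gained the call, 7 reversed and 17 without a call changed sign; the cause was not tested. No paired analysis was possible because the labels give no numbers shared between the groups.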

Other observations

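Except for the count of transcripts over the other splits and the median-of-ratios alternative, the tests in this part were chosen after the results were seen, as were the genes HBEGF and SCFD1. HBEGF, which encodes another ligand of the epidermal growth factor receptor, rose beside AREG, from 1.625 ± 0.155 to 5.7 ± 1.06 FPKM (SD, n = 3 per group; limma adjusted p = 0.000108). Of the 24 genes whose transcripts moved in opposite directions, ZNF317, RPL23AP82 and SCFD1, a gene of vesicle transport, had values above 0 in all 6 libraries for both transcripts. The SCFD1 transcript NM_016106 was at 22.0, 20.4 and 19.1 FPKM in vehicle and 14.6, 14.4 and 15.4 FPKM with IL-33, and NM_182835 at 4.30, 4.34 and 6.07 FPKM and 8.76, 9.32 and 7.04 FPKM.

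TGF-beta response genes stood 0.85, 1.01 and 0.70 above the vehicle mean in the 3 IL-33 libraries (list medians on the log2 scale), against 0.02, -0.02 and -0.01 in the 3 vehicle libraries. An offset between libraries from the deposited scaling is argued against, since the list median was 1.00 after median-of-ratios scaling. A hypothesis is that treated cells made more TGF-beta, and TGFB1 rose by 1.31 on the log2 scale, but TGF-beta protein is not in these data and TGFB1 responds to TGF-beta itself, so the order of events stays open. A difference in growth state between the flasks of the groups cannot be told apart from an effect of IL-33: cell cycle genes had a list median of -0.46, and the labels give no cell density for single flasks.

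More genes fell than rose on the deposited scale. A few abundant genes may take a larger share of fragments and lower all others, and the 100 most abundant genes did take 23.8% of length-weighted FPKM with IL-33 against 22.3% in vehicle. This lowers the rest by only -0.028 on the log2 scale, short of the median change of -0.10, so it is argued against as the whole cause. By abundance, the median change ran from -0.13 in the lowest 20% of tested genes to -0.056 in the highest. The cut at 100 genes does not test a shift of fragments toward abundant genes beyond them. Gene length is argued against too, since the medians of the longest and the shortest 20% of genes differed by 0.009. An offset of the libraries' scaling cannot be told apart from a real fall of many genes: median-of-ratios scaling gave 50% higher calls, but it centres the data by construction and no RNA of known amount is in the files.

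Genes listed at exactly 0 in some libraries and called changed numbered 26, and 22 of them (84.6%) share exon sequence with another gene, against 14.8% of the other tested genes (two-sided Fisher's exact test, p = 5.19e-15). A candidate explanation is that the deposited estimates moved fragments to the overlapping gene: summed over the locus, 14 of the 22 lost their call, 2 were called in the opposite direction and 6 passed in the same direction with smaller log2 changes (ENDOV 1.4 from 4.54, CUTC -0.38 from -3.58, the others given above). Adding the FPKM of an overlapping gene can shrink a change and end a call whether or not fragments were moved. The lost calls and smaller changes alone thus cannot decide between moved fragments and a real change. All 22 had at least 20 fragments per library on average (FPKM times length times depth) in the group with the higher mean. Picking genes by a call already favours high values in that group. The fragments in the libraries listed at 0 are not known, so too few fragments for a value above 0 there cannot be excluded. The 4 without overlap, CSF2, ESM1, MT1A and NPPC, were near 0 in vehicle and called higher with limma (adjusted p 0.000394, 0.00124, 0.00118 and 0.000241). For the 6 that passed after summing, a smaller change at the locus stays open.

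The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 4519 changed genes, where the highest other split gave 1. For transcripts it gave 2396 and the highest other split 20. For gene lists it gave 14, and the highest other split 9. Every other split puts vehicle and IL-33 libraries on both sides, so a difference between the groups widens the spread within each side. Few changed genes or transcripts in those splits are thus no measure of false calls in the real split.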
